A study of Mus musculus with 58 samples.

How the data were processed

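The series holds 58 SORT-seq libraries of mouse embryonic pancreas cells. SORT-seq places sorted single cells in the wells of a 384-well plate and counts transcripts with unique molecular identifiers (UMIs). Per the labels, cells were sorted either as live cells or by the MIP-GFP reporter, in which the mouse insulin promoter drives GFP, at 5 embryonic stages from E12.5 to E18.5. Stage was taken from the developmental stage characteristic. For 12 libraries the title gives another stage, and the title's stage was run as an alternative.

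The deposited values are expected counts: transcripts per gene and well, estimated by the authors from UMIs and not scaled for depth. The values themselves show a correction for UMI collisions, which holds the value of a gene in a well at 1597 or below, except on 1 E18.5 plate made with a larger UMI set. At this ceiling, to within 1 transcript, lay Gcg in 142 of 4009 cells, Ins2 in 110 and Ins1 in 62. Alignment with BWA, use of Seurat and the genome build mm10 are stated in the submitters' processing notes without versions. The table of all wells held 19788 genes and spike-ins, 89 of them spike-ins and 0 mitochondrial. Of its columns, 5760 wells on 15 plates matched libraries of the labels by the plate's name, and 1536 did not and were not used here. The live plates of EP11 and EP14 had transcripts in all 384 wells, though the labels list 3 libraries for each where most plates have 4, so some of their wells may belong to no listed library. The EP17 MIP-GFP plate, also with 3 libraries, had transcripts in 288 wells. A smaller table of wells the authors kept (2097 matched wells, 492 not matched) served only to choose cells in 1 alternative. The wells of the libraries on a plate are pooled under 1 name, so libraries could not serve as replicates.

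Wells were kept as cells with at least 2000 transcripts and 500 genes, which left 4310 cells. Another 8 wells above 5 times their plate's median were left out as possible doublets, and no doublet caller was run because wells were filled by single-cell sorting. Plates held between 1150013 and 9490716 transcripts, and the median per cell ranged from 6782 to 27218. E12.5 and E15.5 each had a deep experiment (EP11, EP10) and a shallow experiment (EP18, EP17). Shares carry Wilson 95% intervals, and a share of 0 carries the limit that 3 counts would give. Intervals and limits cover counting error only.

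A hormone gate held cells whose hormone took at least 1% of the transcripts and at least 3 times the share of any other hormone (insulin as Ins1 plus Ins2, Gcg, Sst, Ppy, Ghrl). Neurog3-gated cells were outside every hormone gate with at least 2 Neurog3 transcripts and 0 Fev, and Fev-gated cells the converse. Genes used for a gate are not reported between those gates. Clusters came from scanpy 1.11.5 (2000 variable genes without cell cycle genes, 30 principal components, 15 neighbours, Leiden resolution 1). The planned naming rule, at least 3 markers among 30 leading genes, left the E12.5 progenitor cluster 19 and the mesenchymal clusters 7, 14 and 15 unnamed. Cluster 3 (duct-like) and cluster 22 (insulin-gated cells of E18.5) were unnamed too. It named cluster 9 pericyte and smooth muscle. It named cluster 2, which held 97.7% of the glucagon-gated cells of EP11, hepatocyte, by Fgb, Serpina1a, Serpina1b and Apoa1. The rule used instead was chosen after seeing the data: the marker list with the largest share of members raised at least 2-fold (log2 of 1) in at least 25% of a cluster's cells, with at least 3 such members. Names of lineages below therefore rest on rebuilt clusters. Cluster 2 was named by the epsilon list, with the alpha list next. Mesenchyme-like cells are those of clusters named by the mesenchyme or the pericyte and smooth muscle list, which overlapped.

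The replicate was the experiment, given by the EP number in the titles. Both sorts of an experiment share its number. Counts were rounded to whole numbers and summed per experiment and group, with at least 10 cells per sum. Sums were tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood test with TMM scaling, filterByExpr and Benjamini-Hochberg adjustment at 0.05. Stage contrasts were fitted over all stages. Stages with 1 experiment add nothing to the spread, which came from EP11 against EP18 and EP10 against EP17. For insulin-gated cells only EP10 and EP17 shared a stage, and for mesenchyme-like cells only EP11 and EP18. A stage with 1 experiment was assumed to vary like the others. MIP-GFP against live was fitted with stage as covariate, and the gate comparisons with the experiment as block. Planned E15.5 against E12.5 contrasts could not be fitted for insulin-gated cells, for the difference between gates and for duct-like cells, which had too few cells at E12.5. The planned slope per day over the stages that had cells is reported instead. Because no label says that embryos or litters differed within an experiment, p-values measure the spread between these experiments.

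Whether the experiment numbers pair the samples was checked by correlating each experiment's deviations from the group means. Correlations ran from 0.219 to 0.487 between sorts, from 0.269 to 0.512 between hormone gates and from 0.257 to 0.552 between precursor gates. All lay above 0.1. Between sorts, EP17 (0.219) correlated better with another experiment (0.23), and all other correlations were highest within the experiment. Group means were taken over all stages, so a shared stage can raise these values. They cannot show that the numbers pair the samples. The pairing comes from the titles.

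Before the data were examined, 33 gene lists, the tests, the gates and the rule for named genes were fixed. The rule takes up to 12 higher and 12 lower genes per comparison by fold, among genes past the threshold with a log2 change of at least 1, a mean of at least 100 CPM, and groups that do not overlap or the same direction in every experiment, plus list members and a fixed panel. For slopes, no overlap was read as the E18.5 sum, from EP16 alone, lying beyond the sums of all other stages. Slope genes named by the rule were thus chosen for standing apart in EP16. The difference between gates has no such reading, so panel genes are given there. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation. The lists described in the text were chosen after all 33 had been tested in the 12 comparisons. Shares were compared by an exact sign-flip permutation test in both directions over 7 experiments, adjusted over 5 hormones. DESeq2 1.42.0 gave the alternative size factors and Wald test. Gene coordinates are GRCm38, the build of the submitters' notes, with 128 of 133 named genes matched.

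Each comparison was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. Of the 4-fold genes, 87% were recovered for MIP-GFP against live, 94% for glucagon- against insulin-gated cells, 89% for Neurog3- against Fev-gated cells, 80% for insulin-gated cells at E18.5 against E15.5, and 66% for glucagon-gated cells at E15.5 against E12.5. Recovery was 43% for tip-like cells, 29% for glucagon-gated cells at E18.5 against E15.5, 9% for mesenchyme-like cells and 3% for the live population. Changes of 4-fold per day were recovered in 98% of genes for the insulin-gated and duct-like slopes and in 96% for the difference in slope. They compound over the days and so are far larger than a 4-fold change between groups. Changes of 2-fold per day were recovered in 97%, 99% and 90%. Smaller slopes, such as many reported below, were not simulated, so their recovery is not known, also for the difference in slope. Alternatives covered scaling, filters, cell minimum, gate width, cluster resolution, stage labels, the authors' cells, sort, block, depth group and each experiment left out.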

Results

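Transcripts of 4310 single cells were counted on 15 plates from mouse embryonic pancreas. The labels list live-sorted and MIP-GFP-sorted libraries numbering 8 and 9 at E12.5, 4 and 4 at E13.5, 3 and 4 at E14.5, 9 and 8 at E15.5, and 5 and 4 at E18.5. At E12.5 and E15.5, 4 of these libraries carry no experiment number, matched no wells and were not analysed here. The others came from 7 experiments: EP11 and EP18 at E12.5, EP12 at E13.5, EP14 at E14.5, EP10 and EP17 at E15.5, and EP16 at E18.5. Plates of EP10, EP11, EP12 and EP14 held between 6619395 and 9490716 transcripts in retained cells, those of EP16 between 3645856 and 6243618, and those of EP17 and EP18 between 1150013 and 2018673. The samples follow endocrine cells as they arise and change, next to the other cells of the organ.

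By the stage characteristic, MIP-GFP plates held mostly glucagon-gated cells at E12.5 and mostly insulin-gated cells at E18.5. The titles of these libraries give another stage, E15.5 for EP11 and EP18 and E14.5 for EP16. At E12.5, glucagon-gated cells made up 73.4% of MIP-GFP cells in EP11 (95% interval 68.5 to 77.7) and 57.2% in EP18, against 1.71% and 5.14% of live cells. No cell at E12.5 passed the insulin gate of 1%: 0 of 349 and 0 of 173 MIP-GFP cells allow shares of up to 0.86% and 1.73%. With a gate of 0.5%, 1 cell passed on each of these plates (0.287% and 0.578%). Insulin-gated cells then made up 12.7% of MIP-GFP cells at E13.5, 17.9% at E14.5, 39.2% and 64.7% at E15.5, and 92.2% at E18.5. Fev-gated precursors, named for a transcription factor of endocrine precursors, reached 32.0% of MIP-GFP cells at E13.5. Over the 7 experiments the glucagon-gated share averaged 26.6% ± 27.2 (SD) in MIP-GFP and 2.19% ± 1.7 in live cells, higher in 7 of 7 (exact sign-flip permutation p = 0.0156, the smallest this design can give; adjusted p = 0.078). The insulin-gated share averaged 32.4% ± 35.0 against 9.23% ± 19.7, higher in 5 of 7 (exact permutation p = 0.0625, adjusted p = 0.156). Neither passed the adjustment over 5 hormones. Both did with a gate of 0.5% (same test, adjusted p = 0.039), where the insulin-gated share was higher in 7 of 7. Both passes hang on the 1 insulin-gated cell on each E12.5 MIP-GFP plate. The glucagon p stayed at 0.0156 in that test, and its adjusted value fell because the insulin p became as small. The live average holds an E18.5 plate coded P6 with 96.7% insulin-gated cells. Without that plate it was 2.58%.

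**Figure D1:**
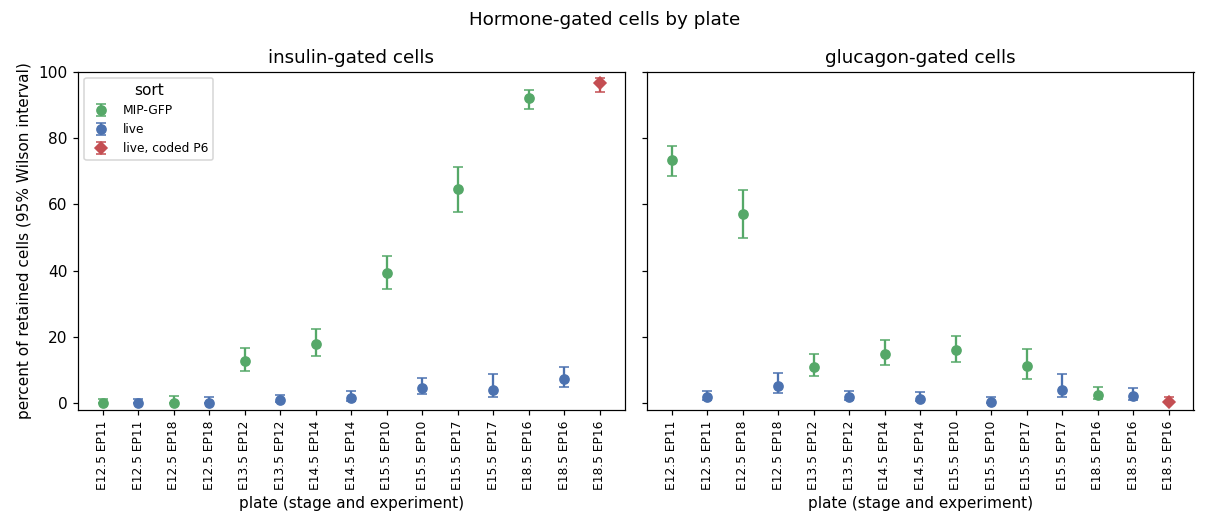
Percent of retained cells in the insulin gate (left) and the glucagon gate (right) per plate, ordered by stage and experiment, with 95% Wilson intervals; green, MIP-GFP; blue, live; red diamond, the E18.5 plate labelled live and coded P6. The glucagon-gated share is 73.4% on the EP11 MIP-GFP plate, and the insulin-gated share is 92.2% on the EP16 MIP-GFP plate.

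MIP-GFP cells carried the endocrine program, and live cells the exocrine and mesenchymal programs. Genes for hormones (Ins1, Gcg), for the granules that store them (Scg2, Ptprn) and for the factors that set endocrine fate (Neurod1, Pax6) were higher in MIP-GFP cells. Acinar enzyme genes such as Ctrb1, collagen genes such as Col1a1 and the progenitor factors Ptf1a and Sox9 were lower. Cartpt, which encodes a neuropeptide precursor, averaged 224 ± 238 CPM in MIP-GFP sums (SD, n = 7), a log2 difference of 4.66 ± 0.667 (SE; adjusted p = 0.000261). The amino acid transporter gene Slc38a5 (chromosome X, 8271133 to 8280179) averaged 4390 ± 3690 CPM, a log2 difference of 3.52. All 26 secretory granule and prohormone processing genes were higher, among them Scg2 (3.68), Ptprn (3.58) and Pcsk2 (3.42), and all 26 were called when adjusted over the list alone (adjusted p = 0.224 with an estimated correlation). Of 24 beta-cell secretion and maturation genes, 20 were higher, led by Ins1 (4.05), Ins2 (3.70), Iapp (3.61) and Ucn3 (3.53), with 20 adjusted over the list alone (adjusted p = 0.224 with an estimated correlation). Ins1 (4.03) and Ins2 (3.54) were not called with stage from the titles. The alpha-cell identity list had 15 of 19 genes higher, such as Irx1 (3.38), and 2 lower, Gc (−4.23) and Gria3 (−1.59), with the same counts adjusted over the list alone. Gria3 was not called without EP10 (−1.43) and was higher, at 1.22 (adjusted p = 0.0137), with the authors' cells, so its direction was not settled. Of 20 endocrine transcription factors, 14 were higher, including Neurod1 (2.96) and Pax6 (2.79), and Hhex (−1.26) was lower, a call lost without EP11, EP12, EP16, EP17 or EP18 (from −1.35 without EP17 to −0.98 without EP16), with the same counts adjusted over the list alone. Both lists had adjusted p = 0.224 with an estimated correlation. Fev was higher (2.58, adjusted p = 0.000193), while Neurog3, the factor that starts endocrine commitment, gave −0.03 ± 0.525 (adjusted p = 0.971).

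Exocrine, matrix and proliferation genes were lower in the same comparison. With Hes1, which carries the Notch signal that holds progenitors back from endocrine fate, and Top2a, used by dividing cells, transcripts of progenitors and of dividing cells were lower in MIP-GFP sums. Of 24 acinar enzyme genes, 23 were lower, with 23 adjusted over the list alone: Ctrb1, a chymotrypsinogen gene, averaged 17.8 ± 19.7 CPM in MIP-GFP sums (SD, n = 7; log2 −7.25, adjusted p = 0.000279), and Cpb1 gave −7.14 (adjusted p = 0.337 with an estimated correlation). The acinar and progenitor factor Ptf1a gave −7.51 and the duct and progenitor factor Sox9 −2.86. Of 36 extracellular matrix genes, 32 were lower, 34 adjusted over the list alone, with Col1a1 at −6.83 and Nid1 at −5.34 (adjusted p = 0.224 with an estimated correlation). All 49 cell cycle genes were lower, and all 49 adjusted over the list alone, such as Plk1 (−3.17) and Top2a (−2.93; adjusted p = 0.224 with an estimated correlation). Of 81 ribosomal protein genes, 58 were lower and 1, Rpl39l (not called without EP10, 3.16, without EP17, 3.23, or with the experiment as block, 3.20, adjusted p = 0.0574), higher; 64 were lower and 1 higher adjusted over the list alone (adjusted p = 0.391 with an estimated correlation). Of 20 Notch pathway genes, 11 were lower, including Hes1 (−4.63) and Jag1 (−3.84), and 4 higher, Dll3 (1.88), Mfng (1.57), Jag2 (1.30) and Maml3 (1.16); adjusted over the list alone, 13 were lower and 4 higher (adjusted p = 0.224 with an estimated correlation). Jag2 was not called without EP10, EP11, EP14, EP17 or EP18 (1.12 to 1.34), nor Maml3 without EP10, EP12, EP14 or EP17 (1.04 to 1.11), nor Dll3 with stage from the titles (1.93). Of 8 hepatocyte markers, 3 were higher, Apoa1 (4.81), Fgb (4.19) and Apoa2 (1.38; not called without EP11, EP12, EP14 or EP18, 1.16 to 1.42), 4 adjusted over the list alone (adjusted p = 0.372 with an estimated correlation), and this list lost its call with the experiment as block (adjusted p = 0.0557) and without EP11 (median 0.922), EP16 (1.661) or EP18 (1.097). Immune-like cells, a measured part of the MIP-GFP plates, made up 36.4% of MIP-GFP cells in EP18 and 3.27% of live cells there. In all, 6252 of 14784 genes differed between the sorts, 2794 higher and 3458 lower in MIP-GFP sums (edgeR).

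In the live population 4 genes were called between E12.5 and E15.5, all of acinar enzyme families. Cpb1, Cela2a and Try10 encode enzymes that acinar cells secrete to digest protein, and all of them rose. Amy2b, of the amylase gene family, rose as well. Amy2b (chromosome 3, 113147656 to 113156727, a locus annotated as an unprocessed pseudogene) rose from 4 transcripts in the 2 E12.5 sums to 351 ± 103 CPM at E15.5 (SD, n = 2; log2 9.64 ± 0.765, adjusted p = 0.0384). The other 3 genes called were the digestive enzyme genes Cpb1 (493 ± 404 CPM at E15.5 and 2 transcripts at E12.5), Cela2a and Try10, the last named although the rule did not select it. Of 25 acinar enzyme genes, 3 rose, and 23 when adjusted over the list alone. Of 24 beta-cell secretion and maturation genes none passed over all genes and 17 rose adjusted over the list alone, as did 11 of 26 secretory granule genes and 7 of 22 unfolded protein response genes. These 4 lists had adjusted p = 0.386 with an estimated correlation. Sst gave 11.79 ± 2.92 (adjusted p = 0.34), as large a change as those called, Ins2 9.97 ± 1.72 (adjusted p = 0.168) and Chga 2.80 ± 0.537 (adjusted p = 0.196), none of them called. The test, which recovered 3% of simulated 4-fold changes, found 4 of 14889 genes, and 980 at an unadjusted p under 0.05. The count was 0 without EP12 (969 at an unadjusted p under 0.05) or EP16 (929), 1 without EP14, 63 without EP11, 106 without EP18, 301 without EP17 and 576 without EP10. It was 0 without the P6-coded plate (958 at an unadjusted p under 0.05). Amy2b was not called without EP12 (9.62) or EP16 (9.61), and Cpb1 (11.07 to 11.12) and Cela2a (11.16 to 11.20) were not called without EP12, EP14 or EP16.

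Glucagon- and insulin-gated cells carried separate identity programs. Glucagon-gated cells expressed Irx1 and Irx2, transcription factors of alpha cells, and the imprinted gene Peg10. Insulin-gated cells expressed Slc2a2, which takes up glucose, Sytl4, which acts in granule release, and the beta-cell factors Pdx1 and Nkx6-1. Genes that fold and check secreted proteins, such as Sdf2l1 and Hspa5, were higher in insulin-gated cells. Apart from the hormones, 3429 of 10709 genes differed. In glucagon-gated cells the transcription factor gene Irx1 (chromosome 13, 71957921 to 71963723) averaged 423 ± 66.2 CPM (SD, n = 5), log2 5.26 ± 0.144 (SE) above insulin-gated cells (adjusted p = 5.07e-16). Irx2 (4.87), Etv1 (4.76) and Peg10 (3.20) were also higher. Insulin-gated cells were higher in the glucose transporter gene Slc2a2 (chromosome 3, 28697903 to 28731359; log2 −6.20 ± 0.216, adjusted p = 1.25e-14), Adra2a (−6.16), Sytl4 (−6.15), the imprinted gene Nnat (−5.20) and Npy (−4.93). Pdx1 (−3.15) and Nkx6-1 (−2.65) were lower in glucagon-gated cells, as was Pax4 (−2.17).

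By group, 15 of 17 alpha-cell identity genes were higher in glucagon-gated cells and 2 lower, also adjusted over the list alone (adjusted p = 0.202 with an estimated correlation). All 9 beta markers tested were lower, also adjusted over the list alone, and of 22 beta-cell secretion and maturation genes 17 were lower, 19 adjusted over the list alone, with Tmem215 at −5.40 and Prlr at −4.43 (adjusted p = 0.102 with an estimated correlation for the second of these lists). All 21 unfolded protein response genes, which serve protein folding in the endoplasmic reticulum, were lower in glucagon-gated cells, also adjusted over the list alone: Sdf2l1 gave −3.69, Creld2 −2.95, Edem1 −2.77 and Atf3 −2.71. Among all lists of the text, the unfolded protein response and the beta markers were the only ones whose call held with an estimated correlation (adjusted p = 0.0375 for each). Endocrine transcription factors went both ways, 4 of 18 higher, including Isl1 (0.86), and 10 lower, including Mlxipl (−2.90), with the same counts adjusted over the list alone (adjusted p = 0.214 with an estimated correlation). Of 20 dissociation and immediate early genes, 15 were lower, such as Nr4a1 (−1.78), and 3 higher, such as Klf2 (1.19), with the same counts adjusted over the list alone. Of 7 hepatocyte markers 6 were higher, also adjusted over the list alone: Fgb 6.29, Afp 5.98 and Apoa1 5.95. Both lists had adjusted p = 0.214 with an estimated correlation. Of 41 cell cycle genes 21 were higher, such as Mcm3 (1.66), and adjusted over the list alone 24 were higher and 1 lower (adjusted p = 0.424 with an estimated correlation). The test called 1608 genes higher and 1821 lower. Small effects rest on 1 experiment: Fev (0.33) and Hspb1 (0.90) were not called without EP14, nor Klf6 (0.33) and Tpx2 (1.14) without EP10.

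**Figure D2:**
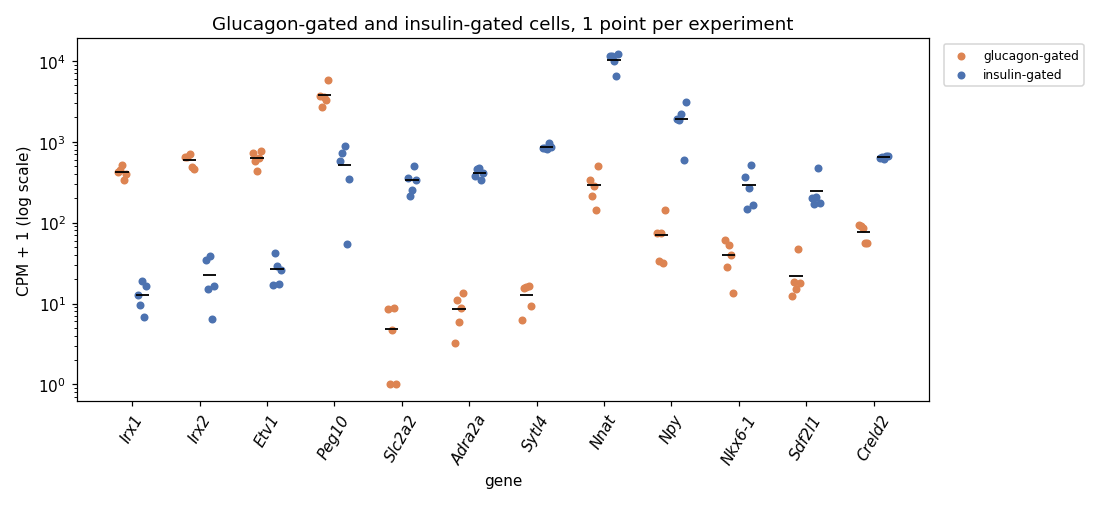
Level of 12 genes in glucagon-gated (orange) and insulin-gated (blue) cells, as CPM plus 1 on a log scale; each point is 1 experiment and each bar the mean. For Irx1 the glucagon-gated sums lie between 338 and 518 CPM and the insulin-gated sums between 5.86 and 17.8 CPM.

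Neurog3-gated and Fev-gated precursors were compared to describe the step between early and later endocrine precursors. Neurog3-gated cells kept Spp1, Sox9 and Hes1, genes of duct-like progenitors, and genes of dividing cells. Fev-gated cells carried granule genes such as Chgb and Irx2, a factor found in alpha cells. Of 10349 genes, 3510 differed, 1773 higher and 1737 lower in Neurog3-gated cells. Spp1 (chromosome 5, 104435118 to 104441050) averaged 1200 ± 634 CPM (SD, n = 4), log2 5.37 ± 0.314 above Fev-gated cells (adjusted p = 5.95e-06), with Col2a1 (6.47), Amotl2 (4.50), Hes1 (3.54), Sox9 (2.75) and Pax4 (1.95) also higher. Higher in Fev-gated cells were Gip (−6.90 ± 0.527, adjusted p = 2.07e-05), Irx2 (−5.61), Tmem27 (−5.43), Peg10 (−5.28), Cryba2 (−4.91) and the granule gene Chgb (−4.51). All 48 cell cycle genes were higher in Neurog3-gated cells, such as Ccnb2 (2.96) and Top2a (2.91), and 73 of 76 ribosomal protein genes, such as Rplp0 (1.17), each count also adjusted over the list alone (adjusted p = 0.340 with an estimated correlation for both). All 10 duct and trunk markers, such as Onecut1 (4.74), and 15 of 18 Notch pathway genes, such as Nrarp (3.59) and Lfng (2.94), were higher, with Maml3 (−1.18) the 1 lower. All 26 granule genes, such as Resp18 (−5.61) and Pcsk1n (−5.32), were lower, as were 20 of 22 beta-cell secretion and maturation genes, such as Iapp (−4.69), and 16 of 17 alpha-cell identity genes, with Gc (2.02) the 1 higher. These 5 lists kept their counts adjusted over the list alone, with 1 more beta-cell gene higher there, and had adjusted p = 0.214 with an estimated correlation. Gc was not called without EP10 (2.33) or EP12 (1.78), nor Maml3 without EP10 (−1.04), EP12 (−0.94) or EP14 (−1.10).

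**Figure D3:**
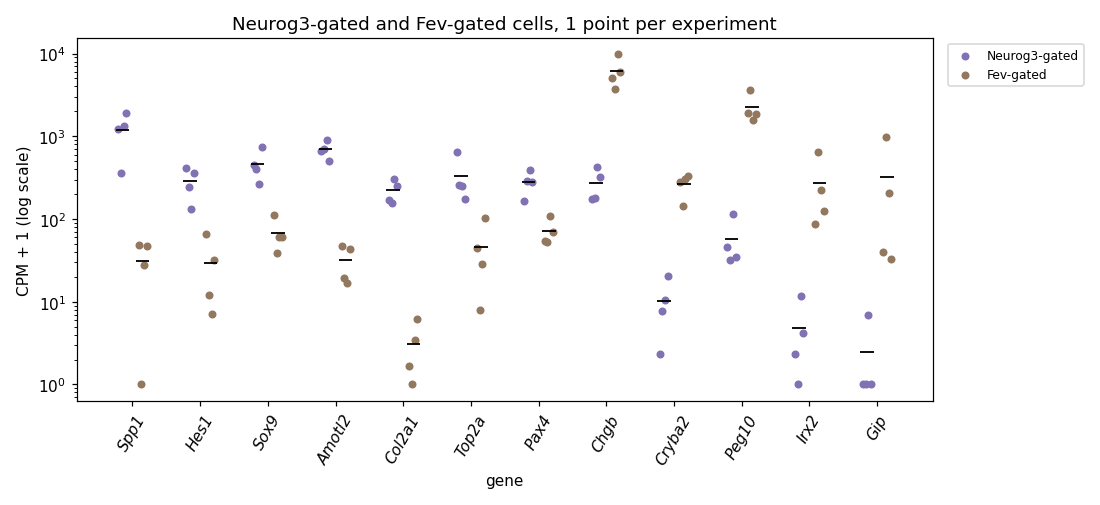
Level of 12 genes in Neurog3-gated (purple) and Fev-gated (brown) cells outside the hormone gates, as CPM plus 1 on a log scale; each point is 1 experiment and each bar the mean. For Spp1 the Neurog3-gated sums lie between 356 and 1890 CPM, and for Chgb the Fev-gated sums between 3750 and 9770 CPM.

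With stage from the characteristic, insulin-gated cells changed from E13.5 to E18.5. With stage from the titles, which give E14.5 for the MIP-GFP libraries of EP16, 0 genes were called (edgeR; 430 at an unadjusted p under 0.05), and without the plates whose titles conflict 550 were. The cells lay in different clusters: 95.9% in EP12, 92.3% in EP14 and 96.7% in EP10 in cluster 1, 82.0% in EP17 in cluster 18, and 37.5% and 61.3% in EP16 in clusters 21 and 22. EP16 also held no transcripts of the sex-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, so the sex of its embryos was not separated from stage. Its 605 insulin-gated cells include those of the P6-coded plate, which held 301 retained cells, almost all insulin-gated. That plate had a larger UMI set and a sort label in doubt, so its make was not separated from stage either. Without the plates whose titles conflict, the E18.5 cells came from it and the other live plate. Ccnd2, a cyclin used in beta-cell division, Prlr, the receptor for prolactin, and Slc30a8, which loads granules with zinc, rose. Gip, which encodes an incretin hormone, and the imprinted gene Peg10 fell. Ccnd2 (chromosome 6, 127125162 to 127152193) rose by 1.04 ± 0.0804 log2 units per day (adjusted p = 0.000401), Prlr by 1.44 and Slc30a8 by 0.68. Gip (chromosome 11, 96024545 to 96030831) fell by 1.19 per day, Peg10 by 0.85 and Pax4 by 0.56. Of 22 beta-cell secretion and maturation genes 6 rose, 12 adjusted over the list alone, including Prlr and Slc30a8. Of 29 cell cycle genes 10 rose, 13 adjusted over the list alone, including Ccnb2 (0.94) and Top2a (0.93). Of 20 dissociation and immediate early genes 10 rose, 15 adjusted over the list alone, including Junb (0.81) and Fosb (0.69). Of 16 imprinted growth genes 3 fell, 5 adjusted over the list alone, including Peg10 and Sgce (−0.63). These 4 lists had adjusted p = 0.292 with an estimated correlation. The slope test called 419 genes rising and 143 falling among 10403. Without EP16, the only E18.5 experiment, it called 1 gene, with 647 at an unadjusted p under 0.05. None of the genes named here was called then: Ccnd2 gave 1.04, Prlr 1.39, Slc30a8 0.90, Gip −0.55, Peg10 −0.38, Pax4 −0.57, Sgce −0.52, Junb 1.13 and Fosb 0.69, and Spp1, which rose by 1.07 over all experiments, gave 0.02, while Top2a and Ccnb2 did not pass the filter and were not tested. The medians of the cell cycle (0.082) and imprinted (0.026) lists were not called either. Without EP12 the count was 259, without EP14 210 and without EP17 1119. By the titles' stage Ccnd2 gave 0.41, Prlr 0.41, Slc30a8 0.32, Gip −1.08, Peg10 −0.65 and Pax4 −0.43.

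With stage from the characteristic, insulin-gated cells of E18.5 differed from those of E15.5 in genes of dividing cells and in imprinted genes. Top2a, used by dividing cells, and Ccnd2 and Prlr were higher at E18.5. Gip and the imprinted gene Peg10 were lower. Stage and cluster were not separated, since the E15.5 cells lay in clusters 1 and 18 and the E18.5 cells in clusters 21 and 22. The 605 cells of E18.5 include those of the P6-coded plate (301 retained cells, almost all insulin-gated), with its larger UMI set and doubtful sort label. Without the plates whose titles conflict, the E18.5 cells came from it and the other live plate. MIP-GFP libraries alone leave it out. Only EP10 and EP17, both of E15.5, shared a stage in this fit. Its p-values rest on the spread between them, and no spread was measured at E18.5. Ccnd2 averaged 598 CPM at E18.5 (n = 1) against E15.5 sums of 56.5 and 90.7 CPM (log2 3.00 ± 0.389, adjusted p = 0.00114), Prlr gave 4.36 and Spp1 4.16. Gip (−4.64), Peg10 (−3.13) and the growth factor gene Mdk (−3.25) fell. Of 44 cell cycle genes 10 rose, 21 adjusted over the list alone, among them Top2a (4.27) and Mki67 (3.43). Of 16 imprinted growth genes 3 fell, 5 adjusted over the list alone (Mest −3.59, H19 −2.75), and of 16 alpha-cell identity genes 3 fell, 5 adjusted over the list alone, including Irx2 (−2.24). Of 20 dissociation and immediate early genes 2 rose, also 2 adjusted over the list alone, Fosb (2.08) and Junb (2.06), and of 22 beta-cell secretion and maturation genes 1 rose, 2 adjusted over the list alone. Of 5 sex-linked genes, Ddx3y was at 0 CPM at E18.5, as were Eif2s3y, Kdm5d and Uty, and Xist at 210 CPM. E18.5 is 1 experiment, EP16, and the other experiments held transcripts of all of these genes. The share of male cells was thus not separated from stage or experiment. These 6 lists had adjusted p = 0.646 with an estimated correlation. The test called 155 genes higher and 58 lower at E18.5 among 11039, 213 in all. The count was 0 with stage from the titles (edgeR; 535 at an unadjusted p under 0.05), 176 without the plates whose titles conflict, 104 with MIP-GFP libraries alone, 126 with a cell minimum raised 2-fold and 45 with DESeq2. With DESeq2, Mki67 (3.53), Mest (−3.63), H19 (−2.70) and Irx2 (−2.19) were not called. Without the plates whose titles conflict, H19 (−2.02), Irx2 (−1.67) and Fosb (1.94) were not called. Without EP14, Fosb (2.07), Gpx3 (1.76), Mapk3 (1.51) and Irx2 (−2.24) were not called.

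**Figure D4:**
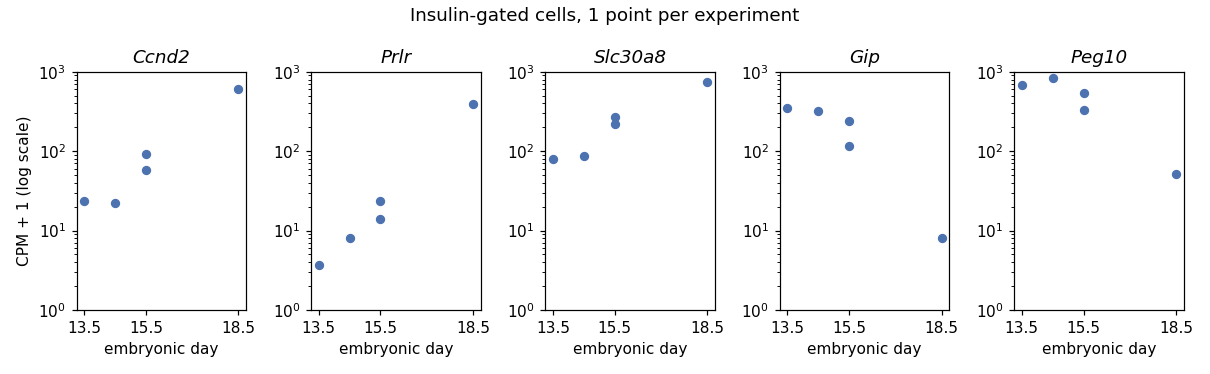
Level of 5 genes in insulin-gated cells by embryonic day, as CPM plus 1 on a log scale; each point is 1 experiment. At E18.5, Ccnd2, Prlr and Slc30a8 lie at 603, 388 and 741 CPM, and Gip and Peg10 at 7.05 and 50.5 CPM.

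With stage from the characteristic, glucagon-gated cells of E15.5 held more Meis2, which encodes a homeodomain factor, and Slc30a8, which loads granules with zinc, than those of E12.5. They held less Cited1, a regulator of transcription, and Mdk, a growth factor of embryonic tissue. The cells lay in different clusters: at E12.5, 97.7% in EP11 in cluster 2, which carries alpha and epsilon markers, and 82.7% in EP18 in cluster 20, and at E15.5, 94.8% in EP10 and 88.5% in EP17 in cluster 0. Meis2 (chromosome 2, 115863064 to 116065839) averaged 917 ± 213 CPM at E15.5 (SD, n = 2), against 51.1 and 64.5 CPM in the E12.5 sums, log2 4.00 ± 0.349 (adjusted p = 0.0083). Slc30a8 (3.27) and Nnat (2.80) rose, while Cited1 (−2.75), Mdk (−2.41) and the collagen gene Col1a2 (−1.95) fell. Of 20 dissociation and immediate early genes 1, Ier2 (2.19), rose, and 12 adjusted over the list alone (adjusted p = 0.439 with an estimated correlation). Of 21 extracellular matrix genes 2 fell, Col4a2 (−3.21) and Col1a2, and adjusted over the list alone 5 fell and 1 rose. Of 8 hepatocyte markers none passed over all genes and 4 fell adjusted over the list alone. Both lists had adjusted p = 0.565 with an estimated correlation. The test called 34 genes higher and 24 lower among 11297. The titles give E15.5 for the MIP-GFP libraries of EP11 and EP18. With stage from the titles 18 genes were called, 1 higher and 17 lower, and none of those named here: Ier2 turned to −0.29, and Meis2 gave 2.25, Slc30a8 3.27, Nnat 2.38, Cited1 −0.75, Mdk −1.15, Col1a2 −1.19 and Col4a2 −0.52. The dissociation and hepatocyte lists then turned round in direction, and neither was called (adjusted p = 0.996 for both). Without the plates whose titles conflict 99 genes were called, and Ier2 (0.64), Col4a2 (−3.01) and both lists were not. It called 0 without EP10 (774 at an unadjusted p under 0.05) and 0 without EP17 (773), 268 without EP11 and 248 without EP18. Without EP10 and without EP17, Meis2 gave 3.74 and 4.22, Slc30a8 3.23 and 3.31, Nnat 3.06 and 2.50, Ier2 1.92 and 2.33, Cited1 −2.44 and −2.97, Mdk −2.17 and −2.67, Col1a2 −1.90 and −1.98, and Col4a2 −3.10 and −3.24, none of them called.

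Cartpt, which encodes a neuropeptide precursor, was lower in glucagon-gated cells of E18.5 than in those of E15.5. Of the 15 cells of E18.5, 8 came from the MIP-GFP plate whose titles give E14.5, and the comparison could not be fitted without it. Cartpt (chromosome 13, 99898489 to 99901091) averaged 805 ± 143 CPM at E15.5 (SD, n = 2) and had 0 transcripts in the 15 cells of E18.5, at least 62.5-fold lower by a limit of 3 transcripts over the group (adjusted p = 0.0302). Of 46 cell cycle genes none passed over all genes or over the list alone, with a median of 1.05. Of 20 dissociation and immediate early genes none passed over all genes and 6 rose adjusted over the list alone. Both lists were called higher by camera at the preset correlation and had adjusted p = 0.687 with an estimated correlation. Among 11297 genes 818 had an unadjusted p under 0.05, and DESeq2 called 8. Cartpt was the only gene called, and was not called without EP10 (adjusted p = 0.724) or EP17 (adjusted p = 0.746). The count was 0 without EP10 (701 at an unadjusted p under 0.05) or EP17 (662), 97 without EP11 and 86 without EP18.

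Whether insulin- and glucagon-gated cells changed differently per day was tested directly. Neither the imprinted gene Peg10 nor Chgb, a granule gene, was called. With edgeR 0 of 10709 genes passed, 564 had an unadjusted p under 0.05, and DESeq2 called 9. With the experiment as block, a fit chosen after seeing the data, 75 genes passed, 27 with a higher and 48 with a lower slope in insulin-gated cells. Peg10 gave −0.87 per day (adjusted p = 0.348) and Chgb 0.40 ± 0.104 (adjusted p = 0.475). Of 17 alpha-cell identity genes none passed over all genes and 5 were lower adjusted over the list alone, with a median of −0.166 (adjusted p = 0.976 with an estimated correlation). This list lost its call without EP16, where its median was −0.07.

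Tip- and acinar-like cells of the live plates changed from progenitor to secretory genes between E12.5 and E15.5. Bhlha15, a factor that builds the secretory apparatus, and Sdf2l1 and Herpud1, which act on unfolded proteins, rose. Spp1, Vim and the cyclin gene Ccnd1, expressed in progenitors, fell. The cells came from cluster 19 at E12.5 (147 of 147 in EP11, 111 of 112 in EP18) and mostly from cluster 13 at E15.5 (71 of 80 in EP10, 71 of 72 in EP17). Another 8 cells of EP10 lay in cluster 11, which held most tip-like cells of E13.5 and E14.5. Stage and cluster were thus not separated, and the enzymes that set cluster 13 apart serve as a check: Cpb1, Cela2a, Try10 and Cela3b had 0 transcripts at E12.5, at least 1290-fold, 1030-fold, 821-fold and 633-fold lower by the limit of 3 transcripts over the group. Bhlha15 rose by 5.16 ± 0.576 (adjusted p = 0.00519) from 3.44 and 10.5 CPM to 215 ± 60.5 CPM (SD, n = 2). Spp1 (−4.42), Serpina1e (−4.06), Ccnd1 (−2.82) and Vim (−2.51) fell. Transcripts of another cell type rose in the same sums, Ins2 by 8.59 (adjusted p = 0.00885) and Ins1 by 6.09 (adjusted p = 0.0109). Of 23 acinar enzyme genes 20 rose and all 23 adjusted over the list alone, of 8 tip progenitor markers 5 rose, 6 adjusted over the list alone, and of 21 unfolded protein response genes 7 rose, 12 adjusted over the list alone, including Sdf2l1 (3.55) and Herpud1 (2.94); these 3 lists had adjusted p = 0.414 with an estimated correlation. Of 5 hepatocyte markers 3 fell, also adjusted over the list alone, including Serpina1a (−3.01; adjusted p = 0.820 with an estimated correlation). The test called 249 genes higher and 128 lower among 11296, with 570 in all without EP11, 688 without EP18 and 227 without EP17. Vim was not called without EP10 (−2.79) or EP17 (−2.29), Ccnd1 not without EP17 (−2.38), and Serpina1a not without EP10 (−2.31).

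Duct-like cells were compared per day from E13.5 to E18.5. Lama4, a laminin of basement membranes, rose, and Gc, which encodes the vitamin D binding protein, fell. The cells came from cluster 3 up to E15.5 and cluster 23 at E18.5. The E18.5 sum, of EP16, held no transcripts of the sex-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, so the sex of its embryos was not separated from stage. Lama4 rose by 1.21 ± 0.139 per day (adjusted p = 0.00254), and Gc fell by 1.40 (adjusted p = 0.00482). Scara3 (1.14), which sets cluster 23 apart, serves as a check. Transcripts of endocrine cell types rose in the same sums, Sst by 2.37, Ins2 by 1.55 and Iapp by 1.02, and so did Ins1 and 3 of 11 granule genes, 5 adjusted over the list alone, including Chga (0.86). They stood together in the E18.5 sum, with Sst at 1522 CPM, Ins2 at 1002, Iapp at 208, Ins1 at 202, Gcg at 181 and Pyy at 158 CPM, whereas Sst was at 0 in EP10 and EP12. Mesenchymal transcripts were high there too, with Col1a2 at 157 CPM and Dcn at 62.4, against 5.9 and 3.6 CPM in EP12. In EP10 they stood at 129 and 33.8 CPM, and in EP17 at 0. Whether the duct-like cells themselves expressed these endocrine and mesenchymal transcripts, or Lama4, which sets a mesenchymal cluster apart, was not tested. Of 20 extracellular matrix genes 1 rose, 10 adjusted over the list alone, of 18 dissociation and immediate early genes 2, including Junb (0.88), 4 adjusted over the list alone, and of 10 duct and trunk markers 1, 2 adjusted over the list alone. These 4 lists had adjusted p = 0.328 with an estimated correlation. The test called 154 genes rising and 43 falling among 9897, with 11 in all without EP16, 25 without EP12, 51 without EP14 and 387 without EP10. Without EP16, Lama4 (1.53), Gc (−0.98), Scara3 (1.14), Ins1 (1.89), Iapp (1.18) and Chga (0.85) were not called, and Ins2 gave 3.09. Without EP12, Gc (−1.68), Sst (2.29), Ins2 (1.34), Ins1 (1.14), Iapp (0.90), Chga (0.81) and Junb (0.70) were not, nor Junb without EP14 (0.82).

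Mesenchyme-like cells of E15.5 held more transcripts of matrix genes than those of E12.5, which lay in another cluster. Lum and Ogn, small proteoglycans that bind collagen, were higher at E15.5, and Hmga2, a chromatin factor of embryonic cells, was lower. At E12.5, 142 of 143 cells in EP11 and 67 of 67 in EP18 came from cluster 15. At E15.5, with 1 experiment (EP10), 89 of 102 cells came from cluster 9 and 10 from cluster 7, so stage and cluster were not separated. Only EP11 and EP18 shared a stage in this fit. Its p-values rest on the spread between them, and no spread was measured at E15.5. Nor did the markers part mesenchyme from pericytes and smooth muscle. Cluster 15 raised 8 of 13 mesenchyme and 6 of 8 pericyte and smooth muscle markers, and its 10 leading genes hold Tcf21, of the mesenchyme list. Clusters 9 and 7 raised all 13 mesenchyme markers and 7 and 5 of 8 pericyte and smooth muscle markers, and their leading genes hold Acta2 and Cspg4 (cluster 9) and Des (cluster 7), of the pericyte list. Lum (chromosome 10, 97565128 to 97572703) stood at 541 CPM at E15.5 against 20.7 and 22.3 CPM at E12.5 (log2 4.64 ± 0.717, adjusted p = 1.12e-07), and Ogn gave 4.65. Hmga2 (chromosome 10, 120361275 to 120476469) fell by 4.40 ± 0.988 (adjusted p = 0.00141), and Id2 (−2.90), Nnat (−2.77) and Cd24a (−2.62) were lower. Agtr2 (6.99), Lama4 (5.24) and Dpt (0 transcripts at E12.5, at least 22.5-fold) set single mesenchymal clusters apart and serve as checks. Of 36 extracellular matrix genes 13 rose, and adjusted over the list alone 21 rose and 1 fell. Of 26 mesenchymal patterning transcription factors none passed over all genes and 1 rose adjusted over the list alone, with a median of −0.615. Transcripts of other cell types moved as well: 5 of 10 acinar enzyme genes rose, 9 adjusted over the list alone, with Ctrb1 at 7.99, Ins2 rose by 9.97, Ins1 by 5.06 (not called without EP16, 4.99) and Iapp by 3.66, and Gcg fell by 5.60. These 3 lists had adjusted p = 0.740 with an estimated correlation. The test called 158 genes higher and 34 lower among 11778, and Nnat (−2.78 and −2.77) and Cd24a (−2.62 in both) were not called without EP14 or without EP16.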

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

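The tests of the E18.5 plate's sort label, of the stage given by the titles, of transcripts per cell and of the hepatocyte list without Trf, the splits of the samples, and the choice of the 6 groups searched for a sample standing apart were all chosen only after the result was seen.

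Insulin-gated cells made up 53.7% of the live cells of EP16 at E18.5, far from the other 6 experiments. The excess lies on the plate coded P6, with 96.7% against 7.19% on the other live plate and 92.2% on the MIP-GFP plate. Values above the ceiling of the other plates, which the larger UMI set of the P6-coded plate allows, were not needed for this excess. With values held to that ceiling, 96.3% of its cells remained in the gate. The gate asks for only 1% of a cell's transcripts, so holding values to the ceiling could hardly move cells out of it. This cannot exclude other effects of the plate's larger UMI set or make, which were not tested. A wrong sort label is a candidate explanation: 100% of the other libraries coded P6 are labelled MIP-GFP, and all those coded P4 live. A biological difference between the plates was not tested. A wrong label, the plate's make and a biological difference all stay open.

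The E12.5 MIP-GFP plates whose titles give E15.5 held glucagon-gated cells and no insulin-gated cell at the gate of 1%. At 0.5%, 1 of 349 and 1 of 173 cells passed the insulin gate. That the titles and not the characteristics give the stage was argued against by the glucagon-gated cells. On the MIP-GFP plates that both labels place at E13.5 to E15.5, between 82.5% and 98.0% of them lay in cluster 0, against 0.781% in EP11 and 0 of 99 in EP18. On the live plates of EP11 and EP18, which both labels place at E12.5, 0 of 6 and 0 of 11 lay there. The embryonic share of beta-globin transcripts could not decide it, since these MIP-GFP plates held 1 and 4 of them. With E15.5 MIP-GFP cells thinned to 2000 transcripts, the lowest insulin-gated share was still 39.2%. The gate is a share of a cell's transcripts, which thinning hardly moves, so this cannot exclude too few transcripts per cell. Both E12.5 MIP-GFP plates had a higher median per cell (27218 in EP11, 9644 in EP18) than the EP17 MIP-GFP plate (8017), with its 64.7% insulin-gated cells. The EP16 MIP-GFP plate has titles that give E14.5. Its insulin-gated share of 92.2% (88.7 to 94.6) argued against them, since the MIP-GFP plates that both labels place at E13.5 to E15.5 held 12.7% to 64.7% and the E14.5 plate 17.9%. An effect of the experiment on clusters and shares was measured only as the spread over these plates. With the stage of the characteristics, the reporter may mark mostly glucagon cells at E12.5, where insulin-gated cells were rare and not shown to be absent, a hypothesis found and tested on the same data.

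Hepatocyte-list genes summed to 1820 and 1150 CPM in E12.5 glucagon-gated cells, against 570 and 589 CPM at E15.5. Tip-like cells of E12.5 held 1690 (EP11) and 451 CPM, so the list is not confined to glucagon-gated cells, and those of EP11 had Alb at 373 and Fgb at 54.0 CPM, whose source was not tested. In the glucagon-gated cells of both experiments liver cells or liver RNA were excluded as the cause, since Alb, abundant in liver, stood at 0.08 of Fgb or less. Free RNA shared by the wells stayed undecided for the whole list, with at most 0.355 of that level in immune-like cells, most of it Trf (267 and 381 CPM), and was argued against without Trf, where the ratio was at most 0.0303. Expression by the early glucagon-gated cells themselves may remain, as a hypothesis.

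Immune-like cells made up 36.4% of MIP-GFP cells in EP18, apart from the other 6 experiments, and no explanation was tested. This and the insulin-gated share of EP16 are the 2 of 6 groups searched in which 1 sample stood apart, and chance does this in about 1 in 20 groups. The slope per day differed between insulin- and glucagon-gated cells in 75 genes with the experiment as block, a fit chosen after seeing the data, against 0 without it (edgeR; 564 at an unadjusted p under 0.05, and 9 by DESeq2).

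Other splits of the samples were fitted for the 3 comparisons with at least 3 samples per group. For MIP-GFP against live, 1 of 100 splits, the real 1, gave as many as 6252 genes. The highest other gave 5382, a split that differs from the real split by exchanging the EP14 live and EP16 MIP-GFP sums and so leaves most samples in place. Among splits that part all 7 experiments' pairs as the real split does, the highest other gave 1. For glucagon- against insulin-gated cells, 1 of 100 splits gave as many as 3429, and the highest other gave 0. For Neurog3- against Fev-gated cells, 1 of the 32 splits that could be fitted gave as many as 3510, and the highest other gave 1. For MIP-GFP against live, the real split stood above every other split fitted, but this does not exclude chance. The others were a random draw, and how many of them part every pair is not given. Splits that do not part the pairs mix sorts and stages otherwise than the real split does. For the gate comparisons these splits cannot decide about chance either. Their fits used the experiment as block, and splits that part every experiment's pair were not counted separately there. With fewer experiments than between the sorts, such splits are too few for the real split to stand out from chance. The gates were also set on transcripts of the same cells, so some difference between them was given beforehand.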

How the results depend on the processing

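The settings with a deep or shallow term and the blocked slope difference were chosen only after the result was seen. Over all alternatives, counts and shares stayed within their bounds in 145 cases, moved in 60 and passed the threshold newly in 2. Named genes were unchanged in 4550 cases, lost their call in 400 and turned round in 5. The unchanged cases include genes called in neither fit. Lists kept their call in 792, lost it in 23 and turned round in 2. Except where said, the cause was not tested.

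With DESeq2 size factors the live population gave 0 genes (983 at an unadjusted p under 0.05). With the DESeq2 Wald test it gave 205, insulin-gated cells at E18.5 against E15.5 gave 45, glucagon-gated cells at E18.5 against E15.5 gave 8, the difference in slope 9 and mesenchyme-like cells 57. Without a filter on low counts the live population gave 361, the insulin-gated slope 1003, insulin-gated E18.5 against E15.5 491, glucagon-gated E15.5 against E12.5 324, glucagon-gated E18.5 against E15.5 89, the difference in slope 3, tip-like cells 969 and the duct-like slope 404.

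A lower cell minimum of 1000 transcripts gave 1 gene in the live population, and a minimum raised 2-fold gave 126 in insulin-gated E18.5 against E15.5. Without the P6-coded plate the live population gave 0 (958 at an unadjusted p under 0.05). The authors' cells gave 47 in the live population, 2 in glucagon-gated E18.5 against E15.5 and 74 for the duct-like slope. MIP-GFP libraries alone gave 104 in insulin-gated E18.5 against E15.5. A hormone gate of 3% gave 337 for the insulin-gated slope and 20 for glucagon-gated E15.5 against E12.5, and the ghrelin share turned to −0.0067. A gate of 0.5% gave differences of 26 for insulin and 25.6 for glucagon, both called (exact sign-flip permutation test, adjusted p = 0.039). Both calls hang on 1 insulin-gated cell on each E12.5 MIP-GFP plate.

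Stage from the titles gave 0 genes for the insulin-gated slope (430 at an unadjusted p under 0.05) and for insulin-gated E18.5 against E15.5 (535), and 18 for glucagon-gated E15.5 against E12.5. There Ier2 (−0.29), Rbms3 (−0.97), Serpina1e (1.22), the hepatocyte list (median 0.745) and the dissociation list turned round, the last lower by its test with a median of 0.565, neither called (adjusted p = 0.996 for both). Without the plates whose titles conflict that comparison gave 99. Gria3 turned to 1.22 between the sorts with the authors' cells.

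A linear slope per day gave 760 for the live population, 273 for glucagon-gated cells and 619 for mesenchyme-like cells. A deep or shallow term gave 114 for the live population, 545 for glucagon-gated cells and 2469 for tip-like cells. With the experiment as block, MIP-GFP against live gave 6904 genes, losing Rpl39l and the hepatocyte list, and the difference in slope gave 75. Without the block, glucagon- against insulin-gated cells gave 2385, losing Fev (0.39), Foxa2, Fxyd6, Klf6 and Nusap1. The block changed no other call of a gene or list named in the text.

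With 1 experiment left out, counts ran from 0 to 576 (live population), 5121 to 6477 (sorts), 1 to 1119 (insulin-gated slope), 183 to 240 (insulin-gated E18.5 against E15.5), 0 to 268 and 0 to 97 (glucagon-gated, early and late), 2415 to 3406 (glucagon- against insulin-gated), 0 to 0 (difference in slope), 2361 to 3398 (precursors), 227 to 688 (tip-like), 11 to 387 (duct-like) and 163 to 194 (mesenchyme-like), and share differences from 16.9 to 27.0 (insulin) and 16.5 to 28.2 (glucagon).

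For insulin-gated E18.5 against E15.5 and for mesenchyme-like cells, only experiments outside the contrast could be left out. These were EP12 and EP14, and for mesenchyme-like cells also EP16. Their narrow ranges therefore do not show that these counts are stable. Not run were single libraries as replicates, stage from the titles for the gate and precursor comparisons, the difference in slope and late glucagon-gated cells, the last without the conflicting plates either, and the deep or shallow term for mesenchyme-like cells, which could not be fitted. Of simulated 4-fold changes, 3% were recovered in the live population, 9% in mesenchyme-like cells and 29% in late glucagon-gated cells, and the cause was not tested. Depth limits what can be said of absent genes: the E18.5 glucagon-gated sum held 258591 transcripts, so 0 transcripts of Cartpt gave a bound of 62.5-fold.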

Other observations

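Other cell types filled much of the live plates. Cells of clusters named by mesenchyme markers made up 38.6% of live cells in EP14, 34.4% in EP10 and 41.7% on the EP16 plate that is not coded P6. Cells of cluster 15, which the naming rule gave to pericytes and smooth muscle though Tcf21, of the mesenchyme list, is among its leading genes, made up 40.5% in EP11 and 31.3% in EP18. The report counts both as mesenchyme-like. Duct-like cells made up 24.2% in EP12 and 22.7% on the same EP16 plate. A cluster of 329 cells, which held 81.1% of the cells of the EP11 MIP-GFP plate, carried Fgb, Igfbp1 and Cartpt beside alpha and epsilon markers, Ghrl among them. It was not compared as a class, because the markers of both cell types name it, but 97.7% of the glucagon-gated cells of EP11 lie in it. The planned naming rule had called it hepatocyte.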
